A study of Danio rerio with 3 samples.

How the data were processed

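Total RNA was extracted from dechorionated whole embryos with a column kit, per the labels' protocols, and libraries were made by a protocol that the labels call standard. Whether polyadenylated RNA was selected, whether the libraries keep strand and how many embryos were pooled are not given in the sources used here, so an effect of poly(A) tail length on the values was not examined. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.2.5 and RSEM 1.2.8 and the genome build GRCz11, without saying which step each served. The deposited table holds 1 column of FPKM (fragments per kilobase of transcript, scaled to the size of the library) per library, per the file headers, made by the authors and rounded to 0.01. How reads shared by near-identical gene copies, such as the hsp70 genes, were divided is not given in the sources used here, so values of such genes are uncertain.

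The table has 26437 rows, of which 1051 have no value in any library, for a reason that is not stated, and were left out. Gene symbols came from the table. The spreadsheet form of 16 symbols had become dates, and those were read from a RefSeq gene table of the assembly GRCz12tu through their gene IDs. That table holds 24195 (91.5%) of the gene IDs and was used only for names, gene types and gene order, since its assembly differs from the authors'. It gave the type protein_coding for 13640 of the measured genes and no type for 636.

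The 3 libraries were grouped by their titles, which give genotype, age and stage. Each of the 3 pairs of libraries was compared by log2((a + 1)/(b + 1)) of the FPKM as deposited, with a pseudocount of 1, over the 14306 genes with a mean of at least 1 FPKM over the libraries. Counts are of genes with a ratio of at least 4-fold on that scale, and list members are counted at 2-fold. With 1 library per group there is no test, standard error or p-value. The 27 gene lists, with 757 names, were fixed before the data were examined. Of the names, 728 matched 1 row, 34 of them through the reference table, and 25 were unmatched or ambiguous, of which 13 are mitochondrially encoded genes, so that list was not analysed here. A few genes and 1 further list are not reported here. The list of differentiated tissue markers had no member with a mean of 1 FPKM, and the list of ovarian and liver markers had 2. For each list with at least 5 measured members the median log2 ratio was given with a 95% order-statistic (binomial) interval over its genes and its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. For the lists of 7 and 8 measured genes (interferon and yolk syncytial layer) the interval runs from the smallest to the largest ratio, with a coverage above 95%. Genes are not replicates, so interval and percentile describe these libraries and not the conditions.

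The genes named in the text were chosen by a rule also fixed before the data were examined: the mutated genes; per comparison the 8 largest ratios in each direction among genes with at least 10 FPKM in the higher library, without symbols that only number a clone or locus; up to 4 members per list with the largest ratio; all members of lists with 10 or fewer measured members; and for lists with little difference up to 3 of the most abundant members. Genes named outside this rule are said to have been chosen after their values were seen.

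Depth cannot be read from FPKM alone. Ratios of low values (0.2 to 0.8 FPKM) peaked at 0.99 for the MZ 4.3 hpf library against wild type, 1.04 for MZ 7 hpf against wild type and 1.05 for MZ 7 hpf against MZ 4.3 hpf, within a tolerance of 1.5%, which describes relative depth only. The peaks held 61 of 1153, 60 of 1423 and 48 of 1219 genes. Only ratios near equality were searched, so a larger difference in depth could not be found. Genes listed at 0 numbered 2985 in wild type, 3999 in the MZ 4.3 hpf library and 2288 in the MZ 7 hpf library. The 100 most abundant genes took 15.2%, 9.79% and 17.3% of the FPKM.

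The scripts were tested on simulated data for the comparison of the MZ 4.3 hpf library with wild type, with 14306 genes and an assumed 20 reads per FPKM. At a coefficient of variation of 0.2, 93% of genes simulated 8-fold apart and 99% of those simulated 16-fold apart passed 4-fold, as did 0% of the equal genes. At 0.4 these shares were 87%, 92% and 0.971%. Equal libraries simulated in 20 draws at both coefficients gave the overlaps expected from the shared library. The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter at a mean of 5 FPKM, protein-coding genes only, thresholds of 2-fold and 8-fold, and 4 other scalings: to equal sums, by the median of ratios, on proteasome genes, and to equal sums without the 1% most abundant genes. The last alternative was also meant to leave out mitochondrially encoded genes, of which the table gave none by name. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.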

Results

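Transcript levels were measured by RNA sequencing of whole zebrafish embryos of the AB strain. There were 3 libraries, 1 per group. The first came from wild-type embryos at 4.3 hours post fertilization (hpf), at dome, the late blastula stage at which the yolk bulges up into the cap of cells. Another came from embryos of the same age that were maternal-zygotic (MZ) double mutants for nup85 and nup133, whose label carries the stage tag 1k. The last came from double mutants at 7 hpf with dome morphology. The design therefore sets the mutant beside wild type at 1 clock age and at 1 morphology, and sets the mutant ages beside each other. At the same clock age, genotype and stage tag differ together, so their effects cannot be told apart. The deposited table held 26437 genes, of which 25386 had FPKM values and 14306 had a mean of at least 1 FPKM over the libraries. FPKM values summed to 424486 in wild type, 397357 in the MZ 4.3 hpf library and 431333 in the MZ 7 hpf library. The table gives no counts, so absolute depth is unknown. The most frequent ratios between low values lay at 0.99 to 1.05, a weak guide to relative depth, since only ratios near equality were searched. With 1 library per group no difference has a replicate check, so none was tested, and genes are named by the size of their difference. Log2 ratios are of FPKM + 1, which understates differences of low genes. FPKM values are relative to the library, so they do not give amounts of RNA per embryo, and a lower value need not mean a loss.

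The mutated genes were read first. The transcript of nup133 (gene 406852), a subunit of the Y-shaped scaffold of the nuclear pore, stood at 11.7 FPKM in wild type, 0.31 in the MZ 4.3 hpf library and 1.91 in the MZ 7 hpf library. Its log2 ratios to wild type were -3.27 and -2.12. The transcript of nup85 (gene 445231), another subunit of that scaffold, stood at 13.2, 10.35 and 9.55 FPKM, with log2 ratios of -0.33 and -0.43. The alleles are not described in the labels, and a mutation need not lower a transcript, so the level of nup85 does not check the genotype. The median log2 ratio of the 31 measured nuclear pore genes was -0.16 (95% interval over genes -0.41 to 0.00) at 4.3 hpf and -0.23 (-0.45 to 0.03) at 7 hpf, with nup85 and nup133 among the 31. The abundant nup62l stood at 134, 111 and 125 FPKM, ndc1 at 96.5, 129 and 114, nup54 at 99.1, 46.2 and 51.4, and nup35 at 109, 147 and 45.4. Import and export receptors and the Ran system, with 35 genes, had medians of -0.07 (-0.39 to 0.10) and 0.03 (-0.27 to 0.40), and the signs of both depended on the scaling.

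At the same clock age but with a different stage tag, most of the transcripts that the embryo's own genome first supplies stood lower in the mutant library. Of the 52 measured genes of the early zygotic list, 44 were at least 2-fold lower than in wild type, 38 were at least 4-fold lower and 1 was at least 2-fold higher. Their median log2 ratio was -3.21 (-3.87 to -2.49), below the medians of all 10000 random lists matched on expression. The zygotic genes nnr and fam212aa stood at 175 and 148 FPKM in wild type and at 0.37 and 0.67 in the mutant. The transcriptional cofactor gene vgll4l stood at 182 against 0.36, and the apolipoprotein gene apoeb at 197 against 1.1. The exception in the list was otx1b, a homeobox gene singled out after its values were seen, at 78.9 FPKM in wild type and 187 in the mutant.

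**Figure D1:**
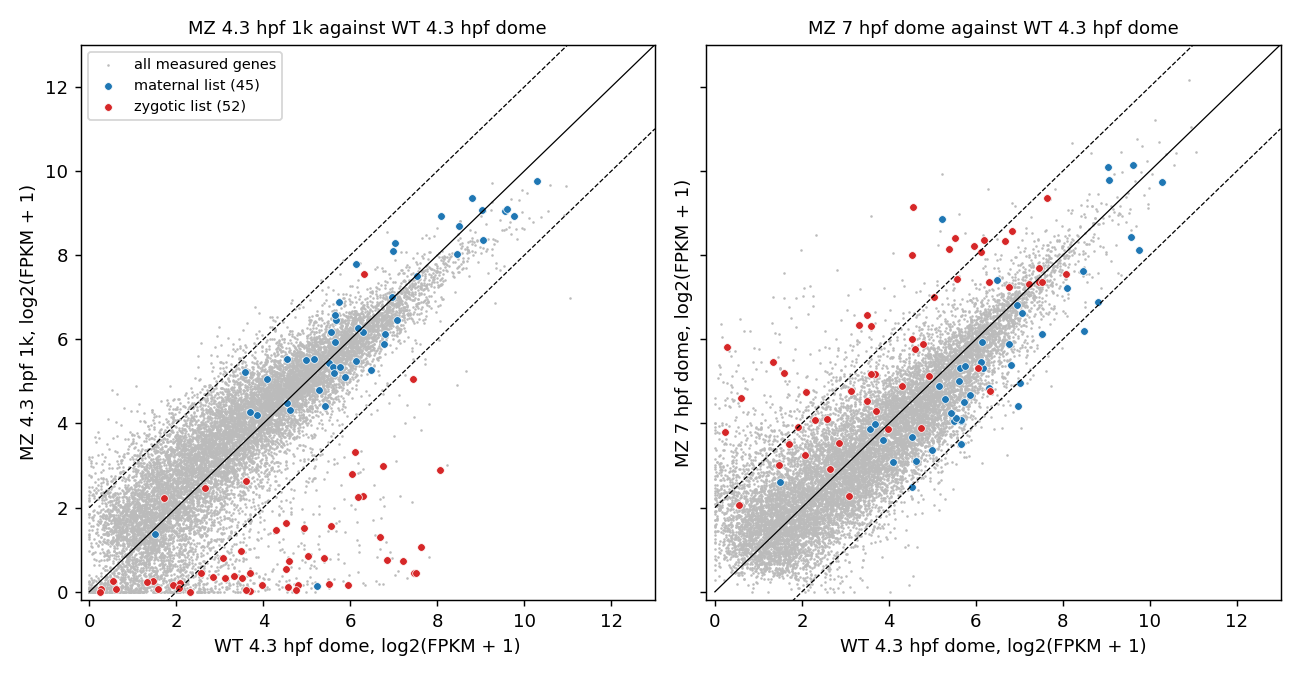
Log2(FPKM + 1) of the 14306 measured genes in the MZ 4.3 hpf library (left) and the MZ 7 hpf library (right) against the wild-type library, with 1 library per axis. Red points are the 52 early zygotic genes, blue points are the 45 maternal genes, the solid line marks equal values and the dashed lines mark 4-fold. Most red points lie far below the diagonal on the left (median log2 ratio -3.21) and above it on the right (median 1.56), while blue points straddle it on the left (-0.05) and lie mostly below it on the right (-0.86).

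The medians of patterning genes were lower in the MZ 4.3 hpf library in every germ layer list, but some abundant members were not lower. Examples chosen after their values were seen are cyp26a1 of the dorsal list, at 36.0 FPKM in wild type and 65.2 in the mutant, and snai1a of the mesoderm list, at 114 and 124. Of 17 ventral and Bmp genes, 12 were at least 2-fold lower and 2 were higher (median -2.80, -3.87 to -0.55), with the ligand gene bmp2b at 26.6 FPKM in wild type and 0.11 in the mutant and the ventral repressor gene ved at 40.8 against 0.75. Of 13 dorsal organizer genes, 10 were lower and 0 were higher (median -2.13, -4.02 to -0.30), with chd, which encodes the Bmp antagonist chordin, at 11.9 against 0.02. Of 22 genes of the Nodal pathway, mesoderm and endoderm, 12 were lower and 1 was higher (median -1.09, -1.86 to -0.67), and the T-box gene tbx16 stood at 60.9 against 0.11. Of 14 ectodermal and early neural genes, 12 were lower and 1 was higher (median -2.79, -4.01 to -1.20), with zic2b at 100.9 against 1.47. Fgf and Wnt genes were lower in 10 of 21 cases and higher in 2, with a median of -0.88 and an interval of -2.14 to 0.20. In that list the Wnt ligand gene wnt11 stood at 26.6 FPKM against 1.11. These lists share members with the zygotic list, from 5 for Fgf and Wnt to 9 for the ventral genes.

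The first epithelium of the embryo and the yolk layer followed the same direction. Of 23 genes of the enveloping layer, the outer epithelium of the blastula, 14 were at least 2-fold lower and 0 were higher (median -1.71, -2.69 to -0.12). The keratin genes krt18 and krt4 stood at 76.8 and 22.6 FPKM in wild type and at 0.16 and 0.09 in the mutant. Only 8 genes of the yolk syncytial layer were measured, 4 lower and 1 higher, and the interval of their median (-1.05) ran from -6.56 to 1.81. Over all genes of that list with values the median was -0.35. The homeobox genes mxtx1 and mxtx2, which act in that layer, stood at 11.1 and 77.2 FPKM against 0.03 and 3.86.

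Maternal transcripts as a list showed no common direction between the 4.3 hpf libraries. The median log2 ratio of 45 maternal genes was -0.05 (-0.43 to 0.33), with 5 at least 2-fold higher and 2 at least 2-fold lower, and its sign depended on the scaling. Among the higher members were sox19b at 129 FPKM in wild type and 313 in the mutant, btg4, a deadenylation cofactor gene, at 69.3 against 221, and dazl, a germ cell translation factor gene, at 10.9 against 36.1. The lowest member was stm, at 36.6 against 0.10, so the mutant library does not show it as supplied by the mother. The 20 genes of the genome activator list had a median of 0.02 (-0.38 to 0.42), again with a sign that depended on the scaling. The pluripotency factor genes nanog and pou5f3 stood at 1244 and 520 FPKM in wild type and at 861 and 533 in the mutant. Among 19 germ plasm genes 4 were higher and 2 lower (median 0.17, -0.30 to 0.86, and -0.03 after scaling by the median of ratios), with tdrd6 at 7.60 against 37.0. Of 35 genes of mRNA decay, 8 were at least 2-fold higher and 0 were lower, with a median of 0.44 (-0.01 to 0.79).

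Basic machinery differed by less than the zygotic and germ layer lists, but the ribosomal and spliceosome medians were larger in size than the maternal one. Of 83 ribosomal protein genes, 8 were at least 2-fold lower and 0 higher, but the median was -0.64 (-0.73 to -0.59). That lay below all 10000 random lists, whose own median was -0.27. The 52 spliceosome genes had a median of -0.52 (-0.64 to -0.42), where random lists had -0.28, with srsf5a at 208 FPKM against 41.8. Cell cycle genes, 42 in number, had a median of -0.15 (-0.41 to 0.01), although the cyclin gene ccnd1 stood at 70.15 against 1.33 and the replication gene mcm6 at 5.39 against 0.13. The adhesion and cytoskeleton list for epiboly, with 24 genes, had a median of -0.19 (-0.52 to 0.01), and rhoab stood at 16.2 against 1.60.

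Across all measured genes, 486 were at least 4-fold lower and 355 at least 4-fold higher in the MZ 4.3 hpf library. The largest higher differences included bcar1 (0.43 FPKM in wild type and 26.5 in the mutant), txlnbb (0.56 and 25.1), tbr1b (0.34 and 16.1), gad1a (0.15 and 12.9) and b4galnt1a (0.53 and 15.4), all low in wild type. The largest lower differences included the zinc finger genes znf1043 (222 and 0.77) and znf995 (106 and 0.14). The counts depend on the pseudocount: with 5 FPKM in place of 1 they were 171 lower and 36 higher. Higher genes made up 42.2% of the genes past 4-fold as deposited and 30.8% after scaling by the median of ratios, which moved the median log2 ratio of all genes from 0.16 to -0.02. Under the other scalings the share was 40.5% to 48.5%.

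At the same morphology, the mutant library held more of the early zygotic transcripts than wild type, not less. Of the 52 zygotic genes, 36 were at least 2-fold higher in the MZ 7 hpf library, 15 at least 4-fold higher and 1 at least 2-fold lower. The median log2 ratio was 1.56 (1.103 to 1.87), above all 10000 random lists. The keratin genes cyt1 and krt4 stood at 0.21 and 22.6 FPKM in wild type and 55.5 and 563 in the mutant, the endoderm regulator gene sox32 at 1.52 against 42.9, and the secreted Bmp modulator gene szl at 0.52 against 23.3. The lower member was otx1b, at 26.3 FPKM in the mutant. With 187 FPKM in the MZ 4.3 hpf library, its values went the way of maternal genes such as sox19b, so they do not bear out its place in the zygotic list.

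Of the lists with a median, the enveloping layer list stood highest relative to wild-type dome. Of 23 genes, 17 were at least 2-fold higher, 16 at least 4-fold higher and 0 lower, with a median of 3.29 (1.93 to 4.58). The keratin genes krt5 and krt92 stood at 2.92 and 2.28 FPKM in wild type and 279 and 108 in the mutant, and the cornified envelope gene evpla at 0.09 against 35.3. Of 8 yolk syncytial layer genes, 7 were higher and 0 lower (median 2.47, 0.08 to 5.31), but the filter on low values keeps some of these genes for their level in this library, and over all genes of the list with values the median was 0.28. In that layer hnf4a, a nuclear receptor gene, stood at 1.81 against 38.6, and mtp, which encodes the lipid transfer protein of lipoprotein assembly, at 0.06 against 41.2. The fibronectin gene fn1a stood at 3.44 against 3.70.

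Germ layer lists were above wild type as well. The ventral list had 13 of 17 genes at least 2-fold higher and 0 lower (median 1.36, 1.03 to 2.43), with vent at 10.4 FPKM in wild type and 95.1 in the mutant. The Nodal, mesoderm and endoderm list had 12 of 22 higher and 1 lower (median 1.29, 0.57 to 2.27), with gata6 at 1.03 against 53.3 and the brachyury gene ta at 8.98 against 80.0. Fgf and Wnt genes were higher in 11 of 21 cases and lower in 2 (median 1.19, 0.35 to 1.61), and fgf8a stood at 3.24 against 25.6. The intervals of the dorsal list (median 0.93, -0.18 to 1.55, 6 of 13 higher) and of the ectodermal list (median 1.02, -0.74 to 1.97, 7 of 14 higher and 2 lower) included 0. In the latter foxg1a stood at 4.79 FPKM in wild type and 0.05 in the mutant. Of 12 genes of the list chosen for the gastrula and later, 6 were higher and 1 lower (median 1.17, 0.67 to 1.77), with the apelin receptor gene aplnra at 23.6 against 91.5. Without the filter on low values the median was 0.30. In wild-type dome 5 of the 26 list members with values already reached 5 FPKM, so the list is not limited to later stages.

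Maternal transcripts were lower in the MZ 7 hpf library than in wild-type dome. Of 45 maternal genes, 21 were at least 2-fold lower and 3 higher, with a median of -0.86 (-1.39 to -0.55), below all 10000 random lists. The gene buc, whose product organizes germ plasm, stood at 124 FPKM in wild type and 20.4 in the mutant, and cd82b at 49.5 against 10.4. The exception with the largest ratio was stm, at 36.6 against 465. With 0.10 FPKM in the MZ 4.3 hpf library, its values followed those of the zygotic list, so they do not bear out its place among maternal genes. Germ plasm genes had a median of -0.74 (-1.51 to -0.11), with 8 of 19 lower and 0 higher, and the linker histone gene h1m stood at 865 against 277. The genome activator list had a median of -0.14 (-0.55 to 0.33) with its members going both ways: sox19b stood at 129 against 30.1, and the chromatin gene hmga1a at 1107 against 2355. Genes of mRNA decay had a median of -0.18 (-0.45 to 0.00) and 4 of 35 were lower, among them cth1 at 446 against 118.

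Ribosomal protein genes had a median of 0.56 (0.42 to 0.69), with 14 of 83 at least 2-fold higher against 1 lower. The spliceosome list had a median of 0.20 (0.08 to 0.40). When the libraries were scaled on proteasome genes these medians became 0.09 and -0.27. Cell cycle genes had a median of 0.19 (-0.13 to 0.49), with ccne2 at 11.9 FPKM in wild type and 98.5 in the mutant and ccnd1 at 70.15 against 356. The epiboly list had a median of 0.19 (-0.20 to 0.66), and the signs of both of these medians also turned under that scaling.

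In all, 597 genes were at least 4-fold higher and 193 at least 4-fold lower in the MZ 7 hpf library than in wild type. Beyond the listed families the largest higher differences included afp4 (0.10 FPKM in wild type and 81.6 in the mutant), lcp1, an actin-bundling protein gene (0.12 and 65.2), znf185 (1.51 and 128) and acer1, a ceramidase gene (0.60 and 72.4). The largest lower differences were in kcnn1b (21.1 and 0.12), rxfp2a (24.1 and 1.1), npdc1b (20.8 and 1.17), psme1 (19.8 and 1.09) and jam2a (34.6 and 2.85). Higher genes made up 75.6% of the genes past 4-fold as deposited and 44.0% when the libraries were scaled on proteasome genes (346 higher and 441 lower), which moved the median log2 ratio of all genes from -0.05 to -0.45. The proteasome genes themselves had a median of 0.45 in this comparison. Under the other scalings the share was 74.2% to 82.1%. With a pseudocount of 5 FPKM the counts were 171 higher and 35 lower.

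**Figure D2:**
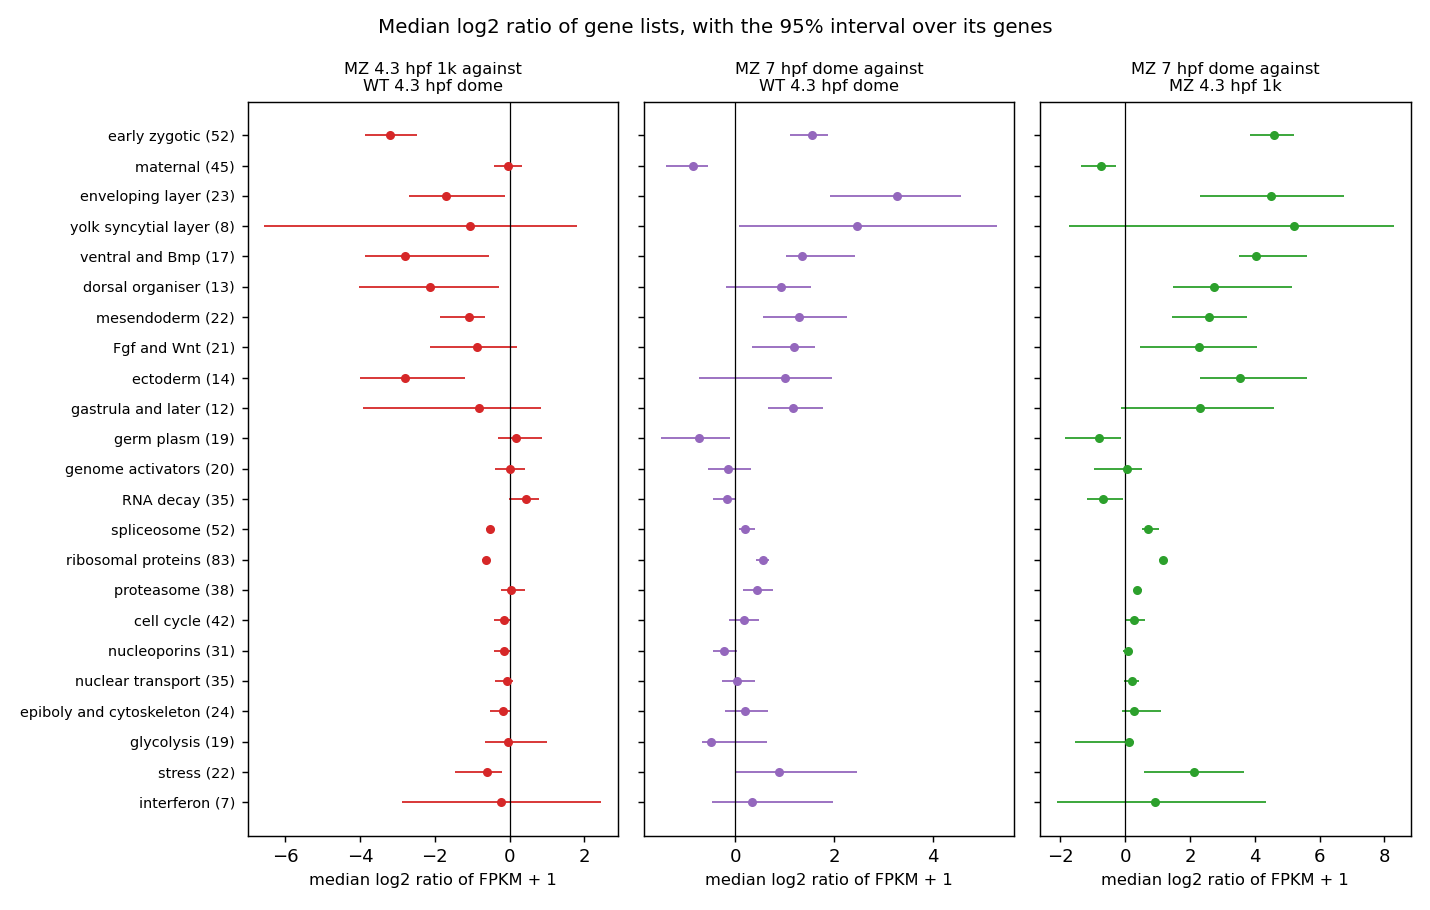
Median log2 ratio of FPKM + 1 for the gene lists reported in the 3 comparisons (points), with the 95% interval over the genes of the list (bars) and the number of measured genes in parentheses. The intervals describe genes within single libraries and not replicate error. The zygotic median lies at -3.21, 1.56 and 4.60 from left to right, and the maternal median at -0.05, -0.86 and -0.74.

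Between the mutant libraries, zygotic transcripts had a far larger share of the 7 hpf library than of the 4.3 hpf library, and maternal transcripts a smaller one. Of 52 zygotic genes, 50 were at least 2-fold higher and 1 lower, with a median log2 ratio of 4.60 (3.84 to 5.22). The gene tbx16 stood at 0.11 FPKM at 4.3 hpf and 297 at 7 hpf, and asb11 at 0.14 and 337. Enveloping layer genes were higher in 20 of 23 cases (median 4.50, 2.31 to 6.76), ventral genes in 15 of 17 (4.03, 3.51 to 5.62), ectodermal genes in 12 of 14 (3.55, 2.30 to 5.62), dorsal genes in 11 of 13 (2.75, 1.48 to 5.15), Nodal, mesoderm and endoderm genes in 18 of 22 (2.59, 1.45 to 3.75) and Fgf and Wnt genes in 13 of 21 (2.29, 0.46 to 4.08). The yolk syncytial layer list was higher in 7 of 8 genes, with a median of 5.22 (-1.73 to 8.29), and hnf4a, mtp and slc26a1 were listed at 0 in the MZ 4.3 hpf library. The gastrula list had a median of 2.32 (-0.13 to 4.60). Without the filter on low values these medians were 0.72 and 0.26.

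Maternal genes were at least 2-fold lower at 7 hpf in 19 of 45 cases and higher in 6, with a median of -0.74 (-1.38 to -0.29). The gene buc stood at 274 FPKM at 4.3 hpf and 20.4 at 7 hpf, sox19b at 313 and 30.1, and the cytoplasmic polyadenylation gene cpeb1b at 45.0 and 4.60. Germ plasm genes had a median of -0.81 (-1.85 to -0.14) and mRNA decay genes of -0.69 (-1.19 to -0.07), with 13 of the 35 decay genes lower and 0 higher, including cnot7, a deadenylase gene, at 16.6 and 1.85. Ribosomal protein genes were at least 2-fold higher in 58 of 83 cases and lower in 1 (median 1.16, 1.03 to 1.26), and spliceosome genes in 19 of 52 (0.71, 0.51 to 1.03). Nuclear pore genes (0.09, -0.07 to 0.17), nuclear transport genes (0.22, -0.04 to 0.42), genome activators (0.04, -0.96 to 0.52), cell cycle genes (0.28, 0.00 to 0.61) and epiboly genes (0.27, -0.09 to 1.099) had small medians whose signs turned under at least 1 scaling.

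At 7 hpf, 1076 of all measured genes were at least 4-fold higher and 670 at least 4-fold lower than at 4.3 hpf. Besides the keratins, the largest higher differences included stm (0.10 and 465 FPKM), polr3gla, an RNA polymerase III subunit gene (0.24 and 501), and akap12b (0.94 and 571), and lye was listed at 0 at 4.3 hpf and stood at 382 at 7 hpf. The largest lower differences, besides buc, were in buc2l (72.2 and 4.32), sh2d5 (78.0 and 4.87), mtus1a (52.6 and 3.49) and ssh2a (82.7 and 6.21). Higher genes made up 61.6% of those past 4-fold as deposited, 78.8% after scaling by the median of ratios and 41.1% after scaling on proteasome genes, which moved the median log2 ratio of all genes from -0.21 to 0.08 and to -0.57. With a pseudocount of 5 FPKM the counts were 435 higher and 161 lower.

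**Figure D3:**
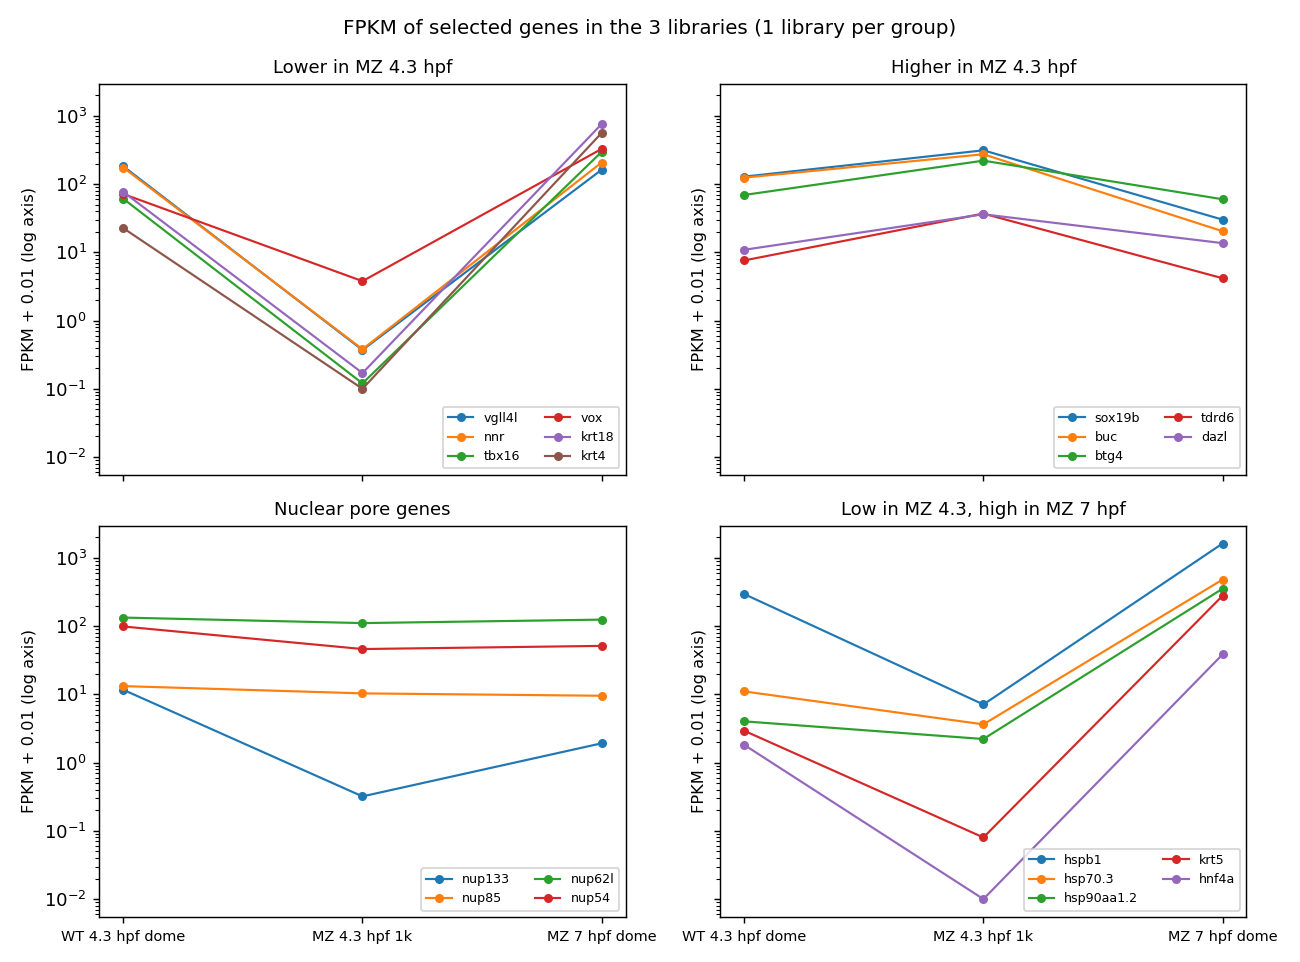
FPKM (plus 0.01, log axis) of selected genes in the 3 libraries, 1 library per group, with lines joining the values of 1 gene. The zygotic gene tbx16 lies at 60.9, 0.11 and 297 FPKM from wild type to MZ 7 hpf, maternal buc at 124, 274 and 20.4, and nup133 at 11.7, 0.31 and 1.91.

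The libraries were also read together, by following the genes that stood apart at 4.3 hpf to the mutant at dome morphology. Of the 486 genes at least 4-fold lower in the MZ 4.3 hpf library than in wild type, 208 (42.8%) lay within 2-fold of wild type in the MZ 7 hpf library, 167 were at least 2-fold above it and 111 at least 2-fold below it. Of these, 61 were still at least 4-fold below, nup133 among them, as were kcnn1b, npdc1b, psme1 and jam2a. Of the 355 higher genes, 200 lay within 2-fold of wild type in the MZ 7 hpf library, 148 were at least 2-fold above it and 61 at least 4-fold above it, such as bcar1, txlnbb, mrvi1 and dscama. The numbers at least 4-fold apart in both depend on the pseudocount: 130 lower and 247 higher at 0.1 FPKM, and 11 lower and 1 higher at 5. Both comparisons use the 1 wild-type library. Equal libraries simulated with a coefficient of variation of 0.4 gave a mean of 3.45 genes lower and 15.2 genes higher in both comparisons, and 0 with a coefficient of 0.2. Independent lists of these sizes would share 6.56 lower and 14.8 higher genes. With 1 wild-type library the control cannot be split, so part of the excess may come from the shared library.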

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

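No paired analysis was possible because each group has 1 library. Directions of the zygotic list in each of the 3 comparisons, and of the maternal list in both comparisons with the MZ 7 hpf library, held under every alternative run: the zygotic medians ranged from -4.33 to -1.86, from 1.16 to 1.72 and from 3.02 to 6.40, and the maternal ones from -1.33 to -0.74 and from -1.16 to -0.40. The limits of the zygotic ranges came from the pseudocount where they left the interval: -4.33 and 6.40 at 0.1, and -1.86 and 3.02 at 5. The maternal median at 4.3 hpf lay between -0.25 and 0.04.

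Counts of genes past 4-fold are given as higher and lower, for MZ 4.3 hpf against wild type, MZ 7 hpf against wild type and MZ 7 hpf against MZ 4.3 hpf. At a pseudocount of 0.1 they were 819 and 982, 1038 and 450, with 1132 lower in the last. At 5 they were 36 and 171, 171 and 35, and 435 and 161, since a larger pseudocount shrinks the ratios of low genes. With a filter at a mean of 5 FPKM, which tests fewer genes, 229, 343 and 667 were higher. Scaling by the median of ratios gave 333 lower in the last comparison. Scaling on proteasome genes gave 346 and 441 in the MZ 7 hpf against wild-type comparison and 1188 lower in the last. At 2-fold the counts were 2377 and 1373, 1986 and 1793, and 1980 and 3175, and at 8-fold 28 and 220, 166 and 17, and 572 and 45.

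Of genes lower in the MZ 4.3 hpf library, 345 of 982 at a pseudocount of 0.1 and 84 of 171 at 5 lay within 2-fold of wild type at 7 hpf. Of the higher ones 321 of 819 and 26 of 36 did, and 115 of 241 after scaling by the median of ratios. Genes 4-fold lower in both mutant libraries numbered 130, 11 and 29 at pseudocounts of 0.1 and 5 and with the filter at 5 FPKM, and those higher in both 247, 1 and 40, and 32 when scaled on proteasome genes. Among the medians whose interval left out 0, that scaling also turned those of the spliceosome list in MZ 7 hpf against wild type (-0.27) and of the cell cycle (-0.14) and proteasome (-0.051) lists in MZ 7 hpf against MZ 4.3 hpf, the last by construction. Medians whose interval included 0 turned under several scalings, such as those of the cell cycle (-0.28) and epiboly (-0.28) lists in MZ 7 hpf against wild type and of the epiboly list (-0.15) in MZ 7 hpf against MZ 4.3 hpf under the same scaling. Counting each median of the other lists once per alternative, 40 combinations left the interval besides the 3 named first, and 548 did not. Counting each ratio of a named gene in the same way, 307 moved by over 1.5-fold, all under another pseudocount, and 3833 did not. The cause was not tested where none is given. Absolute depth is unknown, so the precision of low values cannot be stated.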

Other observations

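Of 22 measured genes of heat shock, unfolded protein and immediate early response, 10 were at least 2-fold higher in the MZ 7 hpf library than in wild type and 3 lower (median log2 ratio 0.88, 0.01 to 2.46), and 8 were at least 4-fold higher. The chaperone genes hsp90aa1.2, hsp70.3, hsp70.1 and hsp70l stood at 4.02, 11.1, 3.15 and 0.27 FPKM in wild type and at 354, 483, 147 and 55.4 in the MZ 7 hpf library, while the most abundant, hspa8, stood at 1327 and 1355. The small heat shock gene hspb1 stood at 295 in wild type, 7.11 in the MZ 4.3 hpf library and 1630 in the MZ 7 hpf library, and at 4.3 hpf 8 genes of the list were at least 2-fold lower and 2 higher (median -0.61, -1.46 to -0.19). Between the mutant libraries its median was 2.12 (0.59 to 3.66).

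Proteasome genes had a median of 0.03 (-0.22 to 0.40) at 4.3 hpf, of no fixed sign under other scalings, 0.45 (0.16 to 0.78) in the MZ 7 hpf library against wild type, and 0.37 (0.29 to 0.53) between the mutant libraries, and when the libraries were scaled on these genes the second came to 0.00 and the last turned, both by construction. The activator subunit gene psme1, in no list, stood at 19.8 FPKM in wild type and 0.98 and 1.09 in the mutants. Glycolytic genes had medians of -0.06 (-0.67 to 1.00), -0.50 (-0.66 to 0.65) and 0.13 (-1.54 to 0.28), the first and last of which changed sign with the scaling. Interferon genes, 7 in number, had medians of -0.24 (-2.88 to 2.45), 0.34 (-0.48 to 1.98) and 0.92 (-2.11 to 4.36), and isg15 stood at 22.0, 2.12 and 63.2 FPKM. The gastrula list had a median of -0.82 (-3.93 to 0.84) at 4.3 hpf, and of -0.19 without the filter on low values. Of the ovarian and liver markers, the steroid enzyme genes cyp11a1 and cyp17a1 stood at 61.8, 124 and 72.3 and at 44.1, 40.0 and 18.3 FPKM.

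The tests of differentiated tissue, maternal transcripts and later stage in what follows were chosen after the results they address were seen. The rule for maternal transcripts was also made stricter after its own first value was seen, and its first form would have favoured that explanation.

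The 355 genes at least 4-fold higher in the MZ 4.3 hpf library than in wild type, such as tbr1b and gad1a, include names known from later tissues. The 4 other scalings did not remove them, since the lowest count was 241. Their factors for the MZ 4.3 hpf library ran only from 0.95 to 1.14, so a larger difference in scale was not examined. The values argue against RNA from differentiated tissue. The highest of 29 markers of muscle, blood, neurons and other tissues stood at 0.96 FPKM in the MZ 4.3 hpf library, while the median of the 355 genes was 14.6. Maternal transcripts still present at an earlier stage remain a candidate explanation: 67.6% of the genes were at least 2-fold lower in the MZ 7 hpf library, against at most 34.1% in 1000 matched random lists and 47.7% in equal simulated libraries, where choosing genes high in 1 library lowers this ratio by itself. The fixed maternal list cannot decide this explanation. It had 0 of 45 genes at least 4-fold higher, but only 2.48% of all measured genes were that much higher. It had 5 genes at least 2-fold higher, against a mean of 3.23 in random lists, where an upper bound set as a share of those lists came to 7. Its genes were also more abundant, with a median of 64.4 FPKM in the MZ 4.3 hpf library over the 46 members with values. The simulated libraries gave a mean of 72.1 genes past 4-fold, but their error is assumed. In the MZ 7 hpf library 148 of the 355 genes were at least 2-fold above wild type and 7 below, which speaks against error in the MZ 4.3 hpf library alone but not against error in the shared wild-type library. Maternal transcripts and error in single libraries therefore cannot be told apart.

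Zygotic genes stood above the wild-type dome level in the MZ 7 hpf library. The 4 other scalings did not remove this difference, since the lowest median over them was 1.16, with a lower limit of 0.64. Their factors for the MZ 7 hpf library ran only from 0.90 to 1.39, so a larger difference in scale was not examined. A later developmental stage than wild-type dome stays open. The 20 gastrula genes of no other list, taken without the filter on low values, had a median log2 ratio of 0.28 (-0.01 to 1.42), with 6 at least 2-fold higher and 1 lower, so they do not establish it. Among them aplnra and aplnrb already stood at 23.6 and 63.2 FPKM in wild-type dome, so the list marks a later stage imperfectly. The 20 genes do not exclude it either, as 8 of them stood below 1 FPKM in both libraries. The other 12 had a median of 1.15, with an interval (0.11 to 1.91) that left out 0 and included the zygotic median of 1.56. Stronger transcription at the same stage might raise such genes too and was not tested, and age and genotype differ together in this comparison.

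The 122 genes at least 4-fold from wild type in the same direction in both mutant libraries, 61 each way (11 lower and 1 higher at a pseudocount of 5 FPKM), include transcripts far lower in the mutants, such as kcnn1b, npdc1b and psme1. Close linkage to the mutated genes does not account for most of them. Genes farther along the same chromosomes, and genes without a place in the reference, were not counted as near, so wider linkage was not examined. Of the 105 placed genes, 1 (0.952%) lay among up to 100 measured genes on either side of nup85 or nup133, against a mean of 2.56 in matched random lists. Equal simulated libraries with an assumed coefficient of variation of 0.4 gave a mean of 18.7 such genes, most of them higher. The mean was 3.45 lower and 15.2 higher, with at most 8 lower and 22 higher in 1 draw. The lower genes thus exceed that assumed error by more than the higher ones. The true error is unknown, so random error in the single wild-type library cannot be told apart from an effect. Chromosome segments that differ between the parents of the libraries stay open too: 13 pairs of these genes lay within 10 measured genes of each other, against a mean of 8.11 in 1000 random lists, where the upper bound fixed in advance as a share of those lists came to 14. A shared effect of the mutations is untested.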
